A study of Mus musculus domesticus and Mus musculus domesticus x Mus musculus castaneus and Mus musculus castaneus with 27 samples.

How the data were processed

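The series profiled polyadenylated RNA of mouse pluripotent stem cells (PSC) and of motor neurons (MN) differentiated from such cells. The lines came from the inbred strains C57BL/6J (BL6), CAST/EiJ (CAST) and 129S6/SvEv (129), and from CAST by 129 hybrids that the labels write as CAS129 and 129CAS. The labels do not say which letters of a hybrid name stand for the mother, and name no batch for the 20 libraries analysed here. Per the labels' protocols, RNA of the 2 cell types was extracted with different kits and treated with DNase. Messenger RNA was then captured on oligo-dT beads, fragmented and copied from random hexamers, and no kit that marks the strand is named there.

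The values used were read counts per gene as deposited by the authors, whole numbers with no normalisation, in a table of 27071 gene identifiers. Per the submitters' processing notes, STAR was used for the 20 libraries analysed here, with the build GRCm38 (mm10). The same notes name TopHat2 2.1.1, SAMtools and HTSeq for 7 other samples, which had no column matched to them and were not analysed here. The counting program of the 20 libraries, the annotation it used, its strand setting, and whether a genome other than GRCm38 was used for CAST, 129 or the hybrids are not given in the sources used here. The table has 28 columns of counts, of which 20 were matched to a sample by name and 8 were not used.

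Gene names, positions and strands were taken from GENCODE M21 on GRCm38 by gene identifier: 27031 identifiers matched and 40 did not. Nanog was not analysed here. Libraries were grouped by cell type and genotype as their titles state: 2 BL6 PSC, 2 CAST PSC, 2 CAS129 PSC, 7 BL6 MN, 1 CAST MN, 2 129 MN, 3 CAS129 MN and 1 129CAS MN. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of replicates looked like 1 library deposited more than once: the lowest chi-square per degree of freedom over 28 within-group pairs was 3.09. The pairs were unevenly close, at 3.66 to 8.69 within CAS129 MN and 3.09 to 139.79 within BL6 MN. This measure also grows with depth, and whether close pairs share a culture was not tested. CAST MN and 129CAS MN are single libraries, and every test that uses them assumes that they vary like the other groups.

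Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, glmQLFit and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were tested if they reached 1 CPM in at least 2 libraries of the fit. MN and PSC were compared over the 17 libraries of BL6, CAST and CAS129 with genotype as a term. Comparisons of MN with PSC within a genotype, and the test of whether that change differed between CAS129 and BL6, came from 1 fit over all 8 groups. Genotypes were compared within the 6 PSC libraries and within the 14 MN libraries. A trend over the number of CAST genomes (0 in BL6 and 129, 1 in the hybrids, 2 in CAST) and a contrast of CAS129 with the mean of its parental strains were also fitted in MN, giving 15 comparisons. Standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. All adjusted p-values of single genes below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Levels are CPM, the counts of a gene scaled to a common library size with TMM factors, given as mean ± SD over the libraries of a group.

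These 22 gene lists were fixed before the data were examined: naive pluripotency, formative and primed pluripotency, motor neuron, pan-neuronal, axon growth and regeneration, activin and TGF-beta, growth inhibition receptors, spinal Hox, neural progenitor, spinal interneuron, sensory neuron, glia, mesenchyme and fibroblast, endoderm and trophoblast, cell cycle, immediate early and stress, imprinted, sex-linked, synaptic transmission, glycolysis, mitochondrially encoded and interferon response. Each list was tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With the preset correlation, camera called 97 of 315 list tests, and 3 with an estimated correlation: spinal Hox (adjusted p = 0.019) and imprinted genes (adjusted p = 0.042) in MN against PSC, and formative and primed genes (adjusted p = 0.016) in the difference of that change between CAS129 and BL6. fry, which asks whether a list moves on balance one way, called 144. Counts of list members are given over all genes tested and adjusted over the list alone.

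The genes named were set by a rule, also fixed before the data were examined. It takes Pou5f1, Nanog, Mnx1, Isl1, Chat, Tubb3, Inhba, Meg3 and Xist where measured, and up to 4 called members of each list with the highest mean CPM. It also takes the 10 largest rises and 10 largest falls of the 4 main comparisons, and 5 and 5 of the others, among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. Genes named outside this rule are said to have been chosen after their values were seen. Some genes were at 0 in every library of a genotype while the other genotypes averaged at least 1 CPM. They numbered 144 for BL6, 48 for CAST, 95 for 129 and 783 for the hybrids. For these genes levels are given in place of fold changes. A count of 0 allows up to 3 counts, which is 0.0479 CPM over the BL6 MN libraries, 0.347 CPM in the CAST MN library and 0.117 CPM in the 129CAS MN library. This limit covers counting error only.

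The procedure was tested on simulated counts drawn with the mean levels, dispersions and library sizes of the real libraries, with 200 changed genes. For MN against PSC over 15078 genes, it recovered 9% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 87.9% of those changed 4-fold, and 7.6% of its calls were genes left unchanged. The same shares were 0%, 1.5% and 18.2% for CAST against BL6 in PSC (13416 genes), 11.9%, 53.7% and 92.4% for CAS129 against BL6 in MN (14415 genes), and 4.5%, 19.4% and 68.2% for CAST against BL6 in MN (14393 genes). The real fits called more than 200 genes each, which loosens the adjustment, so these shares may not hold for them. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, other filters of low counts, robust dispersion, an adjusted p threshold of 0.01, a minimum 2-fold change, leaving out each library in turn, leaving out the X and Y chromosomes, other sets of libraries in the fit, and a block for replicate numbers. Added after the data were seen were fits without the genes at 0 in a genotype, with counts thinned to the shallowest library, and without the CAS129, the BL6 or the hybrid libraries. The planned fit with the 7 TopHat2 samples added was not run, because no column was matched to them. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.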

Results

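Gene expression was measured by RNA sequencing in 6 PSC libraries and 14 MN libraries to describe the transcriptional identity of the lines. PSC are undifferentiated cells able to form all tissues of the body, and MN are the spinal neurons that drive muscle, here made from stem cells in culture. BL6 and 129 are laboratory strains, CAST is an inbred strain of the castaneus subspecies, and CAS129 and 129CAS are first-generation hybrids of the 2 subspecies. Total counts ran from 4.5 M to 13.62 M in PSC and from 5.61 M to 44.57 M in MN. The 129 MN libraries held 41.75 M and 44.57 M counts and the 129CAS MN library 25.69 M, while the CAS129 MN libraries held 5.61 M to 6.29 M. Of 27071 gene identifiers, 22964 had at least 1 count.

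Positions of the genes named throughout are whole annotated genes on GRCm38. Pou5f1 (ENSMUSG00000024406) lies on chromosome 17 from 35506018 to 35510772, Tdgf1 (ENSMUSG00000032494) on chromosome 9 from 110939603 to 110946158, and Zfp42 (ENSMUSG00000051176) on chromosome 8 from 43295063 to 43306980. Isl1 (ENSMUSG00000042258) lies on chromosome 13 from 116298281 to 116309689, Chat (ENSMUSG00000021919) on chromosome 14 from 32408203 to 32465989, and Mnx1 (ENSMUSG00000001566) on chromosome 5 from 29473034 to 29478470. Tubb3 (ENSMUSG00000062380) lies on chromosome 8 from 123411424 to 123422015 and Inhba (ENSMUSG00000041324) on chromosome 13 from 16011851 to 16031621. Meg3 (ENSMUSG00000021268) and Rian (ENSMUSG00000097451) lie on chromosome 12, from 109541001 to 109571726 and from 109603940 to 109661716. Xist (ENSMUSG00000086503) lies on chromosome X from 103460366 to 103483254. Nefm (ENSMUSG00000022054, chromosome 14, 68082590 to 68124846) contains Nefl (ENSMUSG00000022055, 68083863 to 68089095) on the opposite strand. The strand setting of the counting is not given in the sources used here, so values of this pair are uncertain.

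The first comparison asked how MN differed from the stem cells over BL6, CAST and CAS129. Pou5f1, a transcription factor that maintains pluripotency, was 423-fold lower in MN (log2 -8.72, SE 1.04, adjusted p = 7.7e-07, 11 MN against 6 PSC libraries). Its level was 1090 ± 571 CPM in BL6 PSC (n = 2) and 1.15 ± 0.497 CPM in BL6 MN (n = 7). Isl1, a transcription factor of motor neurons, rose by a log2 of 6.12 (SE 0.49, adjusted p = 6.8e-09), and Chat, which makes acetylcholine, by 6.91 (SE 0.63, adjusted p = 3.3e-08). Tubb3, a neuronal tubulin, rose by a log2 of 3.36 (SE 0.27, adjusted p = 8.1e-09). Inhba, which encodes the subunit of activin A, rose by 5.51 (SE 0.53, adjusted p = 5.6e-08).

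Naive pluripotency genes fell together: all 21 tested were lower in MN, both over all genes and adjusted over the list alone. They included Tdgf1, a Nodal co-receptor, with a log2 of -9.75 (SE 1.25), and Esrrb, a nuclear receptor, with -6.33 (SE 0.78). Camera called the list (adjusted p = 1.8e-06), but adjusted p = 0.26 with an estimated correlation. Of 13 formative and primed genes, 8 fell and 2 rose, the same adjusted over the list alone, with Nodal at -6.53 (SE 0.77) and Sall2 at 2.91 (SE 0.27), and the list was not called (adjusted p = 0.1). All 18 cell cycle genes fell, also adjusted over the list alone, among them the DNA topoisomerase Top2a by a log2 of -5.00 (SE 0.58) and the replication helicase subunit Mcm2 by -4.76 (SE 0.44). Camera gave this list adjusted p = 2.3e-07, and adjusted p = 0.26 with an estimated correlation. Of 16 glycolysis genes, 13 fell and 1 rose, the same adjusted over the list alone. Aldoa fell by a log2 of -2.87 (SE 0.19) and Ldha by -2.01 (SE 0.19), and the list had adjusted p = 0.00022, or adjusted p = 0.26 with an estimated correlation.

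Neuronal genes rose. Of 18 motor neuron genes 17 rose, and of 20 pan-neuronal genes 19, the same numbers adjusted over the list alone. The receptor Ret rose by a log2 of 6.03 (SE 0.40) and the intermediate filament Prph by 5.38 (SE 0.54). The neurofilament gene Nefm rose by 7.47 (SE 0.45). Mnx1, a motor neuron transcription factor, rose by 1.55 (SE 0.51, adjusted p = 0.011), a call that ended without CAST MN replicate 1 (1.19, adjusted p = 0.067). All 29 synaptic genes rose, also adjusted over the list alone, with the vesicle proteins Syt4 at 9.50 (SE 0.64) and Syp at 6.52 (SE 0.67). Camera called these 3 lists with adjusted p = 8.2e-06, 1.5e-07 and 4.9e-09, and with adjusted p = 0.14, 0.26 and 0.26 with an estimated correlation. Dcx, a microtubule protein of young neurons, stood at 234 CPM in BL6 MN and at 0 counts in BL6 PSC, where the floor over the group is 0.113 CPM.

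Genes of axon growth and its control also changed. Of 29 axon growth genes 21 rose and 4 fell, of 26 activin and TGF-beta genes 17 rose and 4 fell, and of 26 growth inhibition receptors 22 rose and 2 fell, the same adjusted over the list alone. Basp1, a growth cone protein, rose by a log2 of 2.27 (SE 0.21), the growth factor Tgfb3 by 6.07 (SE 0.66), and Rtn4, which encodes Nogo, by 1.91 (SE 0.22). Ptprf, a receptor phosphatase, fell by 0.99 on the log2 scale (SE 0.17). Camera gave these lists adjusted p = 0.00022, 0.0055 and 9.6e-06, and adjusted p = 0.19, 0.26 and 0.076 with an estimated correlation. Of 22 spinal Hox genes, which set position along the spinal cord, 20 rose, also adjusted over the list alone, with Hoxa5 at 6.01 (SE 0.41) and Hoxb8 at 6.16 (SE 0.37). This list had adjusted p = 2.3e-07, and adjusted p = 0.019 with an estimated correlation.

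Markers of other cells were measured in the same libraries. Of 15 mesenchyme and fibroblast genes 14 rose, and 15 adjusted over the list alone. The mean log2(CPM + 1) of this list was 8.49 to 9.53 in the BL6 MN libraries, where that of motor neuron genes was 4.14 to 5.12. What mix of cells the MN libraries hold, and whether it differs between genotypes, was not tested. The smooth muscle actin Acta2 rose by a log2 of 6.27 (SE 1.06) and the collagen Col1a1 by 3.14 (SE 0.52), and the list had adjusted p = 8.2e-05, or adjusted p = 0.27 with an estimated correlation. Counts in the next lists were the same adjusted over the list alone. Of 17 spinal interneuron genes 11 rose and 1 fell (adjusted p = 0.017, and adjusted p = 0.26 with an estimated correlation), with the glycine transporter Slc6a5 at 8.16 (SE 0.87). Lists not called by camera were neural progenitor (6 of 15 rose and 5 fell, adjusted p = 0.64), sensory neuron (4 of 9 rose and 1 fell, adjusted p = 0.15) and glia (5 of 12 rose and 3 fell, adjusted p = 0.73). Endoderm and trophoblast genes (5 of 12 rose and 2 fell, adjusted p = 0.64), immediate early and stress genes (1 of 18 rose and 8 fell, adjusted p = 0.73) and interferon response genes (3 of 14 rose and 3 fell, adjusted p = 0.57) were not called either. None of the 3 mitochondrially encoded genes tested passed edgeR's test (adjusted p = 0.37 for the list).

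Of 23 imprinted genes, 19 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.0001, and adjusted p = 0.042 with an estimated correlation). Peg3, a paternally expressed zinc finger gene, rose by a log2 of 2.81 (SE 0.24). Rian, a maternally expressed noncoding RNA, rose by 2.57 (SE 0.37). Its neighbour Meg3 had 0.78 (SE 0.48, adjusted p = 0.15), and without BL6 PSC replicate 1 it had 1.69 (adjusted p = 0.0012). Xist, the RNA of X inactivation and the only sex-linked marker measured, fell by a log2 of -4.20 (SE 0.34). In all, 11642 of 15596 genes were called, 5634 higher and 6008 lower in MN. Because the RNA of the 2 cell types was extracted with different kits, kit and cell type cannot be told apart.

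**Figure D1:**
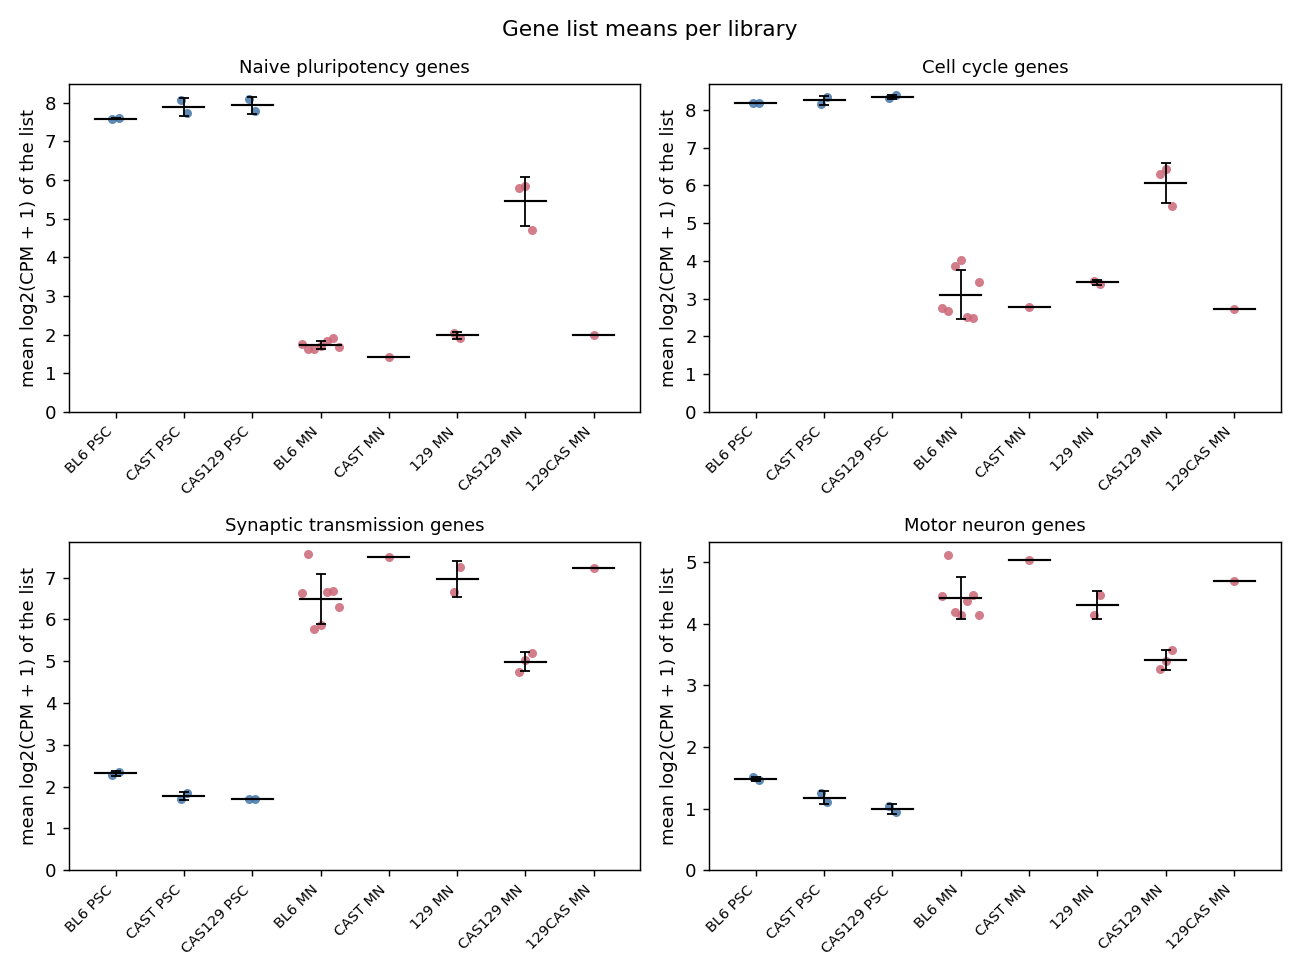
Mean log2(CPM + 1) of 4 gene lists (y axis) in each of the 20 libraries (points, blue for PSC and red for MN), by group, with black lines for group means and error bars for SD, absent for the groups of 1 library. The naive pluripotency mean lies at 4.71 to 5.85 in the CAS129 MN libraries and at 1.43 to 2.05 in the other MN libraries.

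The same change was then tested within each genotype. Pou5f1 fell by a log2 of -9.88 in BL6 (SE 0.40, adjusted p = 1.6e-11) and of -2.65 in CAS129 (SE 0.42, adjusted p = 5.9e-05). Isl1 rose by 5.53 (SE 0.59) in BL6, 5.28 (SE 0.71) in CAS129 and 8.03 (SE 0.71) in CAST. Tubb3 rose by 3.38 (SE 0.40), 3.15 (SE 0.41) and 4.35 (SE 0.48), and Inhba by 4.80 (SE 0.65), 7.23 (SE 0.82) and 6.01 (SE 0.80) in the same order. Called genes numbered 11123 in BL6 (5699 higher), 8618 in CAS129 (4824 higher) and 8875 in CAST (4806 higher). CAST had 1 MN library. The log2 changes of BL6 and CAS129 correlated across 15846 genes (r = 0.741, rho = 0.772), and genes are not independent replicates. Of 7274 genes called in both, 7082 moved the same way.

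Whether the change from PSC to MN differed between CAS129 and BL6 was tested directly. Of 21 naive pluripotency genes, 17 had a higher change in CAS129 than in BL6 and 1 a lower one, the same adjusted over the list alone. The difference was a log2 of 7.23 for Pou5f1 (SE 0.66, adjusted p = 3.4e-06), 10.45 for Tdgf1 (SE 0.68, adjusted p = 7.4e-08) and 10.96 for the RNA-binding protein gene Lin28a (SE 0.76, adjusted p = 1.5e-07). In CAS129 MN, Pou5f1 stood at 140 ± 64.6 CPM, Tdgf1 at 184 ± 88.1 and Lin28a at 109 ± 43.7 (n = 3), and in BL6 MN all 3 were at or below 1.15 CPM. In CAS129 PSC the levels were 878 ± 151, 885 ± 13.2 and 45.4 ± 7.27 CPM (n = 2), so the mean of Lin28a was higher in the MN than in the PSC of this hybrid. Camera called the naive list (adjusted p = 3.3e-15, and adjusted p = 0.066 with an estimated correlation). Of 13 formative and primed genes 6 had a higher change, and 10 adjusted over the list alone (adjusted p = 4.9e-06, and adjusted p = 0.016 with an estimated correlation). Of 18 cell cycle genes 15 had a higher change, and 16 adjusted over the list alone (adjusted p = 6.6e-13, and adjusted p = 0.17 with an estimated correlation), with Mcm2 at 3.15 (SE 0.51).

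For neuronal genes, the difference between CAS129 and BL6 was -0.23 for Tubb3 (SE 0.48, adjusted p = 0.84) and -0.26 for Isl1 (SE 1.17, adjusted p = 0.99). Of 18 motor neuron genes 1 had a higher and 2 a lower change, and of 20 pan-neuronal genes 1 and 3, both also adjusted over the list alone. Of 29 synaptic genes the numbers were 1 and 1, and 1 and 0 adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.23, 0.11 and 0.06), which does not show that the changes were alike. The Eph receptor gene Epha4 had a lower change by a log2 of -3.26 (SE 0.34). Meg3 had 2.33 (SE 0.60, adjusted p = 0.013), which did not pass without BL6 PSC replicate 1 (1.37, adjusted p = 0.11), CAS129 MN replicate 3 (1.68, adjusted p = 0.056) or CAS129 PSC replicate 2 (1.94, adjusted p = 0.11). In all, 2883 genes were called, 2164 higher and 719 lower. With RLE scaling the split was 1258 and 1116 and with DESeq2 1659 and 1610, as the median over all genes moved from 0.26 to 0.00 and -0.03. The count was 1715 without CAS129 MN replicate 1, 1703 without replicate 2, and 1409 without CAS129 PSC replicate 2.

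**Figure D2:**
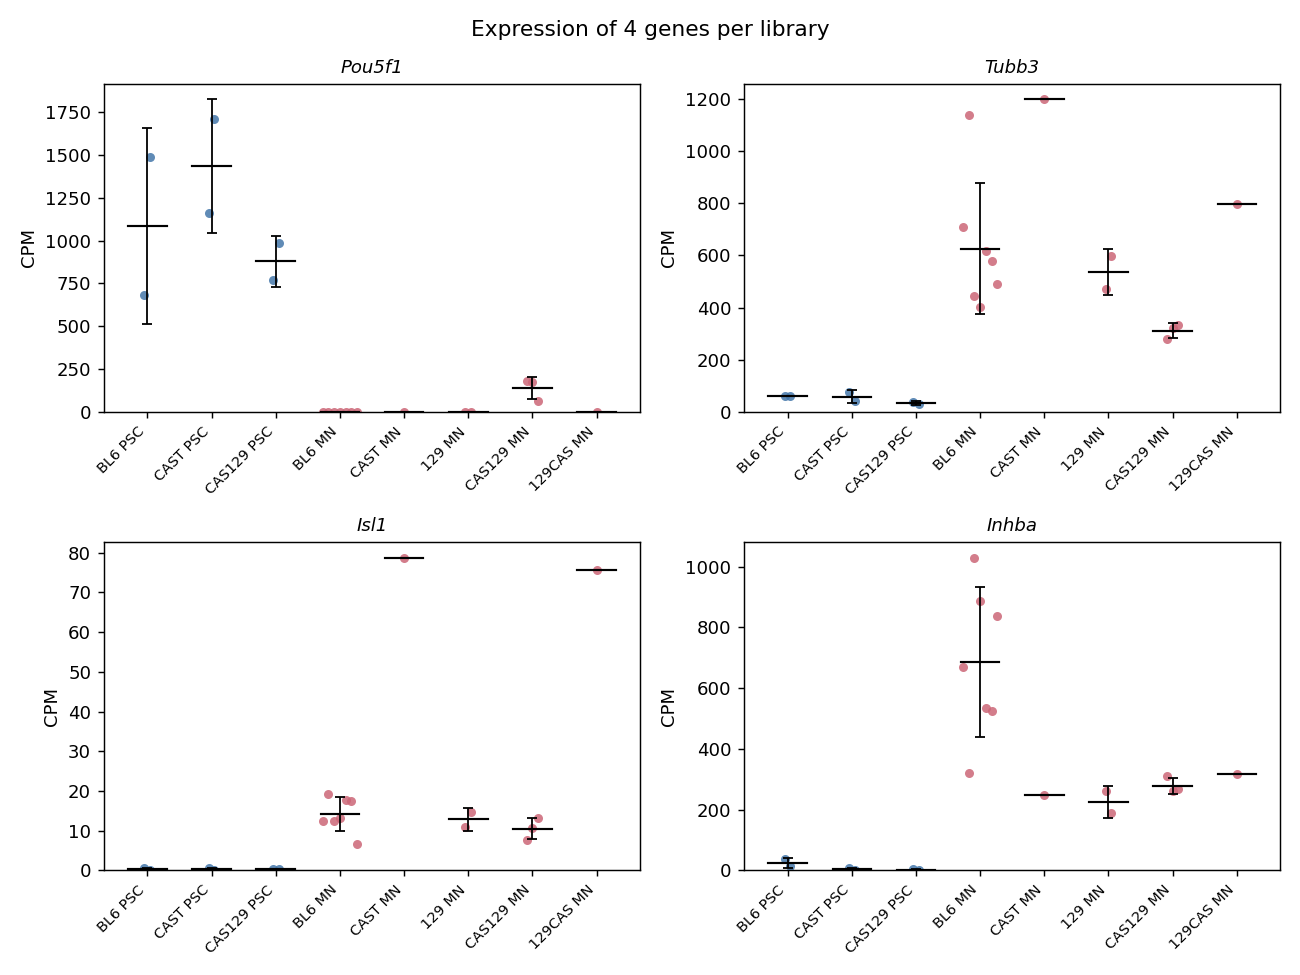
Level in CPM (y axis, linear) of Pou5f1, Tubb3, Isl1 and Inhba in each of the 20 libraries by group, with points for libraries (blue PSC, red MN), black lines for means and error bars for SD. Pou5f1 has a mean of 140 CPM in CAS129 MN and of 1.15 CPM in BL6 MN.

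Stem cells of the genotypes were compared next. CAST PSC expressed Zfp42, a zinc finger gene of naive cells, at 482 ± 41 CPM against 67.3 ± 16.7 CPM in BL6 (log2 2.87, SE 0.32, adjusted p = 0.0014, n = 2 and 2). Tdgf1 was lower in CAST (log2 -2.82, SE 0.32, adjusted p = 0.0014), while Pou5f1 differed by 0.42 (SE 0.42, adjusted p = 0.55) and Tubb3 by 0.00 (SE 0.36, adjusted p = 1). The small heat shock gene Hspb1 stood at 514 ± 129 CPM in BL6 and 0.75 ± 0.352 CPM in CAST (log2 -9.35, SE 0.52). It was low in every group but BL6, at 4.34 CPM in CAS129 PSC and 0.168 to 2.2 CPM in MN, against 452 CPM in BL6 MN. The cause was not tested. Slc7a11, which encodes a cystine transporter and was chosen after its values were seen, stood at 0.917 ± 0.53 and 360 ± 24.5 CPM (log2 8.62, SE 0.54). The imprinted gene Grb10, an adaptor of growth factor receptors, was lower in CAST by a log2 of -2.85 (SE 0.34), and Meg3 was higher by 2.70 (SE 0.48, adjusted p = 0.011), a call that ended without CAST PSC replicate 1 (2.68, adjusted p = 0.053).

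Of 22 axon growth genes 5 were lower in CAST PSC, and 8 adjusted over the list alone (adjusted p = 0.0036, and adjusted p = 0.5 with an estimated correlation). Of 10 neural progenitor genes 3 were lower, and 5 adjusted over the list alone (adjusted p = 0.0058, and adjusted p = 0.5 with an estimated correlation), with Olig1, a progenitor transcription factor, at -7.97 (SE 0.91). Of 21 naive pluripotency genes 4 were higher and 2 lower, and 6 and 2 adjusted over the list alone. Between CAST and BL6, 1455 of 13795 genes were called, 792 higher and 663 lower. The number fell to 316 without CAST PSC replicate 1, 368 without replicate 2 and 657 without BL6 PSC replicate 2.

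CAS129 PSC also had more Zfp42 than BL6 PSC, 703 ± 52.6 CPM (log2 3.43, SE 0.33, adjusted p = 0.00014), and less Lin28a (log2 -2.56, SE 0.30, adjusted p = 0.00041). The DNA methyltransferase gene Dnmt3a was lower by a log2 of -3.16 (SE 0.36), and Stmn2, a microtubule regulator of neurons, by -2.57 (SE 0.31). Of 16 pan-neuronal genes 9 were lower and 2 higher, and 11 and 2 adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.59 with an estimated correlation). Without genes at 0 in a genotype, 7 of 14 were lower and 1 higher. Of 22 axon growth genes 10 were lower, and 13 lower and 1 higher adjusted over the list alone (adjusted p = 0.02, and adjusted p = 0.59 with an estimated correlation). Called genes numbered 3553, 1203 higher and 2350 lower, and 2132 and 2135 without CAS129 PSC replicates 1 and 2.

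Against CAST PSC, CAS129 PSC had more Tdgf1 (log2 2.63, SE 0.32, adjusted p = 0.00058) and less Sox11, a neuronal transcription factor (log2 -5.72, SE 0.64, adjusted p = 0.00038). Of 16 pan-neuronal genes 7 were lower, and 9 adjusted over the list alone (adjusted p = 0.0095, and adjusted p = 0.74 with an estimated correlation). Without genes at 0 in a genotype, 3 of 14 were lower, and 7 adjusted over the list alone. Of 1933 called genes 313 were higher and 1620 lower, and with upper-quartile scaling 580 and 1418. Without genes at 0 in a genotype 946 were called, and without CAST PSC replicates 1 and 2 or CAS129 PSC replicate 1 the counts were 1112, 1119 and 1181. The glycolytic gene Pgk1 stood at 1490 CPM in BL6, 1500 CPM in CAST and 0 counts in CAS129 PSC, where the floor is 0.3 CPM. Genes were left out only if every hybrid library was at 0, so similar losses remain in the counts without them. Vars, chosen after its values were seen, stood at 399 CPM in CAST PSC, 0 counts in CAS129 PSC and 0.0412 CPM in 129CAS MN.

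Among MN, the 129 strain was compared with BL6. The 129 MN libraries held 41.75 M and 44.57 M counts, against 7.6 M to 10.36 M in BL6 MN. Of 233 genes inside a gene on the opposite strand, 64 were over 8-fold lower in 129 MN. A difference in preparation or counting cannot be told apart from strain here, or in the other comparisons that use 129 MN. Krt8 and Krt18, keratins of simple epithelia, were higher in 129 by log2 values of 2.34 (SE 0.49, adjusted p = 0.0022) and 2.35 (SE 0.43, adjusted p = 0.00087), with Krt8 at 503 ± 147 CPM (n = 2) against 90 ± 61.5 CPM (n = 7). Foxa2, a transcription factor of endoderm and floor plate, was higher by 3.20 (SE 0.36). Of 12 endoderm and trophoblast genes 10 were higher, also adjusted over the list alone (adjusted p = 0.00012, and adjusted p = 0.44 with an estimated correlation). Of 17 spinal interneuron genes 7 were lower and 2 higher, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.14). The lower ones included Gad1, which makes GABA, at -4.71 (SE 0.85) and the vesicular transporter Slc32a1 at -5.24 (SE 0.97). Tubb3 differed by -0.36 (SE 0.31, adjusted p = 0.4) and Isl1 by -0.28 (SE 0.31, adjusted p = 0.51).

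Of 14 interferon response genes 8 were higher in 129 MN, also adjusted over the list alone, with the peptide transporter Tap1 at 1.09 (SE 0.12). The list had adjusted p = 0.00027, and adjusted p = 0.44 with an estimated correlation. Of 15 mesenchyme genes 9 were lower, and 10 adjusted over the list alone (adjusted p = 0.0011, and adjusted p = 0.44 with an estimated correlation). All 3 mitochondrially encoded genes were lower, also adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.44 with an estimated correlation), but each was at 0 in a genotype. Inhba was lower in 129 (log2 -1.75, SE 0.39, adjusted p = 0.0033), a call that ended without 129 MN replicate 2 (-1.53, adjusted p = 0.065). Called genes numbered 5397 of 14837, 2717 higher, and 3219 and 2764 without 129 MN replicates 1 and 2.

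The single CAST MN library was compared with the 7 BL6 MN libraries. Isl1 stood at 78.8 CPM in CAST and 14.1 ± 4.38 CPM in BL6 (log2 2.40, SE 0.34, adjusted p = 0.00046), and Onecut2, another motor neuron transcription factor, was higher by 3.11 (SE 0.30, adjusted p = 2e-05). Aldh1a2, which makes retinoic acid, was lower by a log2 of -3.82 (SE 0.62). Among Hox genes, Hoxc6 and Hoxa7 were lower by -3.70 (SE 0.42) and -5.02 (SE 0.66), and Hoxb4 was higher by 1.26 (SE 0.22). Pou4f1, a sensory neuron transcription factor, was higher by 2.90 (SE 0.39).

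In this comparison 5 of 29 synaptic genes were higher, also adjusted over the list alone (adjusted p = 0.00061, and adjusted p = 0.81 with an estimated correlation). Of 15 mesenchyme genes 4 were lower, and 9 adjusted over the list alone (adjusted p = 0.00023, and adjusted p = 0.61 with an estimated correlation), with the receptor gene Pdgfrb at -2.19 (SE 0.41). Of 9 sensory neuron genes 3 were higher, and 4 adjusted over the list alone (adjusted p = 0.0067, and adjusted p = 0.29 with an estimated correlation). Tubb3 had 0.87 (SE 0.37, adjusted p = 0.15) and Inhba -1.54 (SE 0.52, adjusted p = 0.072). Without BL6 MN replicate 2 both passed, at 1.09 (adjusted p = 0.0045) and -1.65 (adjusted p = 0.0077). Called genes numbered 1831, 855 higher and 976 lower, and 3805 without that replicate.

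CAS129 MN expressed stem cell genes above BL6 MN. Pou5f1 was higher by a log2 of 6.82 (SE 0.36, adjusted p = 3.8e-09), Tdgf1 by 10.13 (SE 0.43, adjusted p = 5.3e-10) and Zfp42 by 8.02 (SE 0.36, adjusted p = 8.3e-10), with 3 and 7 libraries. Of 21 naive pluripotency genes 17 were higher, also adjusted over the list alone (adjusted p = 6e-08, and adjusted p = 0.81 with an estimated correlation). Of 18 cell cycle genes 16 were higher and 2 lower, also adjusted over the list alone (adjusted p = 2.8e-05, and adjusted p = 0.81 with an estimated correlation), with Top2a at 3.96 (SE 0.49). Without genes at 0 in a genotype, such as Pcna, all 16 were higher. Acta2, the smooth muscle actin, was higher by 1.12 (SE 0.32), but did not pass in 1 fit of all 8 groups (1.23), and 5 of 15 mesenchyme genes were higher and 2 lower, also adjusted over the list alone.

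Neuronal genes were lower in the same CAS129 MN libraries. Tubb3 was lower by a log2 of -1.10 (SE 0.27, adjusted p = 0.0038), Stmn2 by -2.92 (SE 0.36, adjusted p = 1.6e-05) and Syp by -3.99 (SE 0.52, adjusted p = 2.6e-05). Of 20 pan-neuronal genes 19 were lower and of 29 synaptic genes 28, also adjusted over the list alone. Both lists had adjusted p = 5.3e-05, and adjusted p = 0.81 with an estimated correlation. Without genes at 0 in a genotype, such as Map2, Mapt and Scn2a, 17 of 18 and 27 of 28 were lower. Of 18 motor neuron genes 12 were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.064). Isl1 differed by -0.54 (SE 0.29, adjusted p = 0.12), and by -0.66 without BL6 MN replicate 7 (adjusted p = 0.022). Of 29 axon growth genes 16 were lower, also adjusted over the list alone (adjusted p = 0.0088, and adjusted p = 0.81 with an estimated correlation). Inhba was lower by -1.41 (SE 0.32, adjusted p = 0.002), at 279 ± 26.3 CPM against 686 ± 248 CPM. Called genes numbered 8834 of 14837, 4008 higher and 4826 lower, and 8006 without genes at 0 in a genotype.

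Meg3 was low in BL6 MN, at 15.9 ± 5.29 CPM (n = 7), and stood at 846 ± 449 CPM in CAS129 (n = 3), 1570 ± 470 CPM in 129 (n = 2), 1890 CPM in CAST and 2010 CPM in 129CAS. The log2 difference from BL6 was 5.62 in CAS129 (SE 0.31, adjusted p = 5.7e-09), 6.48 in 129 (SE 0.33, adjusted p = 1e-08) and 6.81 in CAST (SE 0.36, adjusted p = 1.1e-07). Rian stood at 48.9 ± 11 CPM in BL6 and 1280 ± 114 CPM in CAS129 MN (log2 4.61, SE 0.18, adjusted p = 2.7e-10).

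**Figure D3:**
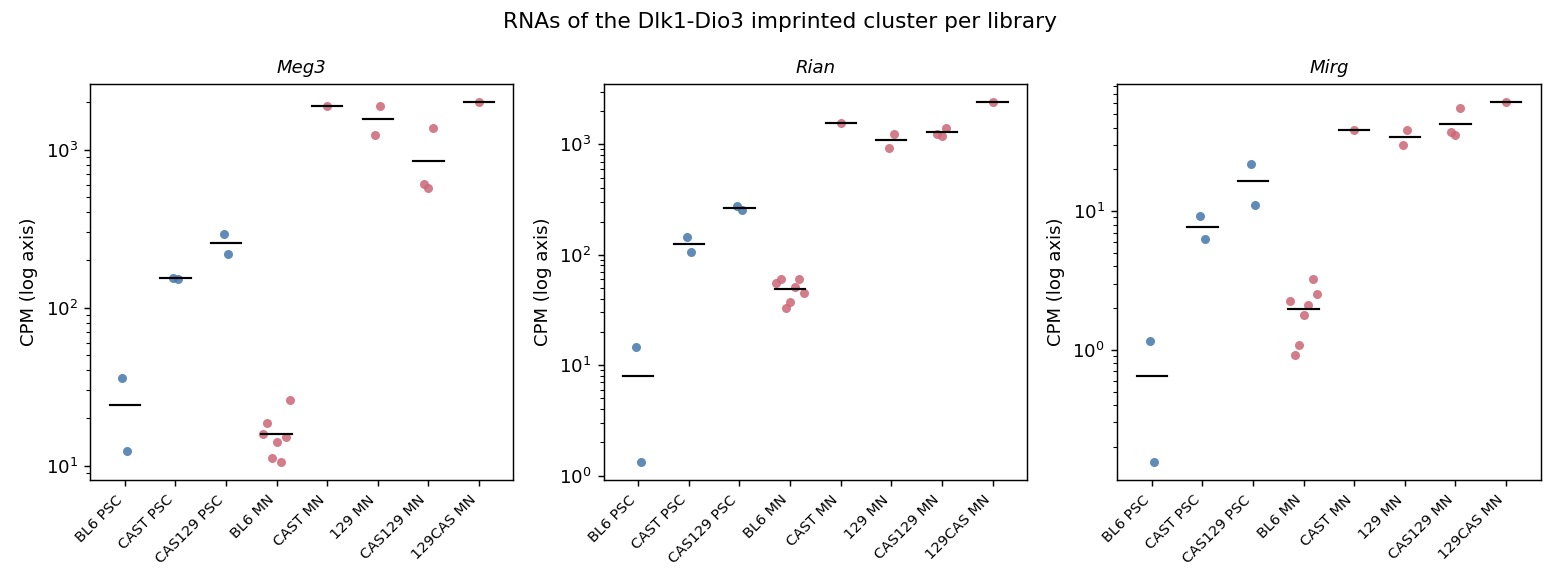
Level in CPM (y axis, log scale) of Meg3, Rian and Mirg in each library by group, with points for libraries and lines for means. Every BL6 MN library lies below every other MN library for all 3 genes.

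The hybrid was also compared with the 129 strain and with the mean of its parental strains. Against 129 MN, CAS129 MN had more Zfp42 (log2 5.62, SE 0.50, adjusted p = 7.7e-07) and less Onecut2 (log2 -4.33, SE 0.37, adjusted p = 4.9e-07) and Krt7 (log2 -7.55, SE 0.53, adjusted p = 7.3e-08). Of 21 naive genes 18 were higher (adjusted p = 2.2e-07, and adjusted p = 0.61 with an estimated correlation) and of 29 synaptic genes 27 were lower (adjusted p = 0.00028, and adjusted p = 0.68 with an estimated correlation), also adjusted over the list alone. In the same libraries 11 of 15 mesenchyme genes were higher and 1 lower (adjusted p = 0.0021), and 15 of 18 cell cycle genes were higher and 2 lower (adjusted p = 6.7e-05), also adjusted over the list alone, both with adjusted p = 0.61 with an estimated correlation. Called genes numbered 8408, 3742 higher and 4666 lower. Against the mean of CAST and 129, Isl1 was lower by -1.60 (SE 0.33, adjusted p = 0.0012), Tubb3 by -1.36 (SE 0.32, adjusted p = 0.0027) and Robo2, an axon guidance receptor, by -3.84 (SE 0.32). All 20 pan-neuronal genes were lower, or all 18 without genes at 0 in a genotype, also adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.61 with an estimated correlation), and 18 of 21 naive genes were higher, 20 adjusted over the list alone (adjusted p = 4.1e-07, and adjusted p = 0.61 with an estimated correlation). Of 15 mesenchyme genes 12 were higher and 1 lower, 13 and 1 adjusted over the list alone (adjusted p = 0.00068), and of 18 cell cycle genes 16 and 2, also adjusted over the list alone (adjusted p = 0.00013), both with adjusted p = 0.61 with an estimated correlation. Inhba differed by 0.24 (SE 0.36, adjusted p = 0.6). This contrast called 8688 genes, 4169 higher and 4519 lower.

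The other hybrid, 129CAS, was a single library and was compared with CAS129 MN. Pou5f1 had 0 counts in 129CAS MN, with a floor of 0.117 CPM, against 140 CPM in CAS129 MN. Isl1 was higher in 129CAS by a log2 of 2.70 (SE 0.40, adjusted p = 0.0005), Robo2 by 3.67 (SE 0.36, adjusted p = 1.8e-05) and Syt4 by 2.26 (SE 0.46, adjusted p = 0.0034). Of 21 naive genes 16 were lower, also adjusted over the list alone (adjusted p = 6.3e-08, and adjusted p = 0.31 with an estimated correlation). Of 18 cell cycle genes 15 were lower, 16 adjusted over the list alone (adjusted p = 3e-08, and adjusted p = 0.31 with an estimated correlation). Of 29 synaptic genes 23 were higher, 26 adjusted over the list alone (adjusted p = 3e-08, and adjusted p = 0.44 with an estimated correlation), and 9 of 18 motor neuron genes were higher, also adjusted over the list alone (adjusted p = 0.0032, and adjusted p = 0.34 with an estimated correlation). Of 15 mesenchyme genes 12 were lower, also adjusted over the list alone (adjusted p = 6.6e-06, and adjusted p = 0.31 with an estimated correlation), with the fibrillin Fbn1 at -3.04 (SE 0.45), or -2.88 and not called in 1 fit of all 8 groups. Called genes numbered 4498, 2162 higher and 2336 lower.

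A trend over the number of CAST genomes was tested in MN, the subspecies difference named in the title of the series. Aldh1a2 fell by a log2 of -1.67 per CAST genome (SE 0.26, adjusted p = 0.0062), Hoxc6 by -2.19 (SE 0.43, adjusted p = 0.019) and Hoxa7 by -2.38 (SE 0.48, adjusted p = 0.02). The groups without a CAST genome differed in level, with Hoxc6 at 46.8 CPM in BL6 and 13.6 CPM in 129 MN, and Hoxa7 at 33.6 CPM in BL6 and 6.22 CPM in 129 MN, the latter no higher than the 6.93 CPM of CAS129 MN. Kcnk9, a potassium channel, fell by -5.30 (SE 0.69, adjusted p = 0.0022), from 130 CPM in BL6 and 26.2 CPM in 129 to 0.324 CPM in CAST MN. Runx3, a sensory neuron transcription factor, rose by 1.66 (SE 0.33, adjusted p = 0.019). Its level did not climb with each CAST genome, at 8.71 CPM in CAS129, 6.26 CPM in 129CAS and 7.34 CPM in CAST MN. It was 1.44 CPM in BL6 and 2.5 CPM in 129 MN. None of these 5 called genes passed without the BL6 libraries or without the hybrid libraries, alternatives chosen after the data were seen. Inhba had -0.83 (SE 0.30, adjusted p = 0.13), and -1.17 without the CAST MN library (adjusted p = 0.044). Tubb3 had 0.13 (adjusted p = 0.78) and Isl1 1.07 (SE 0.30, adjusted p = 0.07).

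Of 21 naive genes 9 had a positive slope past the threshold, and 16 adjusted over the list alone, but their levels did not follow the number of CAST genomes. Tdgf1 stood at 184 CPM in CAS129 MN, 0.165 CPM in 129CAS MN and 0 counts in CAST MN, and Utf1 at 81.7, 0.37 and 0.108 CPM. Of 22 spinal Hox genes 3 fell, and 6 fell and 1 rose adjusted over the list alone. Camera called none of the lists. Of 14837 genes 439 were called, 225 higher and 214 lower, 51.3% higher against 61.7% with upper-quartile scaling and 62.3% with DESeq2. DESeq2 called 2071 genes. The count was 6109 without the CAST MN library, 165 without the hybrid libraries, and 0 by edgeR without the BL6 libraries, where 1451 genes had an unadjusted p under 0.05. It was 196, 211, 222, 213, 213 and 222 without BL6 MN replicates 1, 3, 4, 5, 6 and 7, and 200, 213 and 209 without CAS129 MN replicates 1, 2 and 3.

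**Figure D4:**
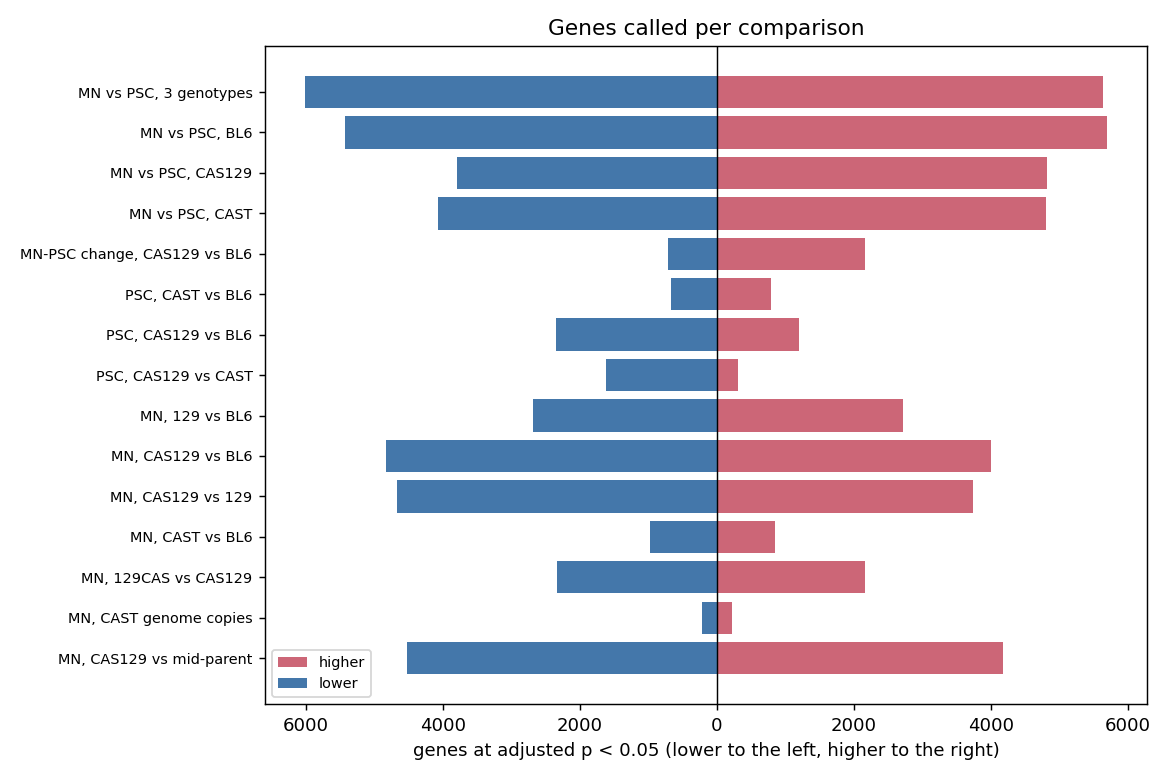
Number of genes called by edgeR in each of the 15 comparisons, with bars to the left for genes lower and to the right for genes higher. The longest bar to the left is that of MN against PSC over 3 genotypes, with 6008 lower and 5634 higher. The longest to the right is that of MN against PSC in BL6, with 5699 higher. Bars are short for the trend over CAST genomes, with 214 lower and 225 higher.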

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

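The tests of explanations in this part were chosen after the results were seen, while the comparison of the MN change between CAS129 and BL6 was planned. In 29 values tested over the 7 BL6 MN libraries, 4 set replicate 2 apart from the others, where chance sets a library apart in about 1 in 20. Its motor neuron list mean was 5.12 against 4.14 to 4.47 in the others, a gap of 0.663 of the whole range, and its growth inhibition receptor mean was 6.28 against 5.73 to 5.86, a gap of 0.764. Mnx1 stood at 11.2 CPM there, with a gap of 0.578 of the range, and Tubb3 at 1140 CPM, with a gap of 0.587. Mnx1 belongs to the motor neuron list, and both lists hold Ngfr and Nrp1. The 4 values are therefore not independent, and their number cannot be set against 1 in 20 as separate hits.

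The change from PSC to MN differed between CAS129 and BL6 for 2883 genes, by a log2 of 7.23 for Pou5f1, 10.96 for Lin28a, 10.45 for Tdgf1 and 2.33 for Meg3. The count was 1715, 1703 and 1409 without CAS129 MN replicates 1 and 2 and CAS129 PSC replicate 2. The Meg3 difference did not pass without BL6 PSC replicate 1 (1.37), CAS129 MN replicate 3 (1.68) or CAS129 PSC replicate 2 (1.94).

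Stem cell transcripts were present in the CAS129 MN libraries: over 95 transcripts of CAS129 PSC, the CAS129 MN level had a median of 12.6% of the PSC level, at 14.8%, 14.3% and 6.7% in the 3 libraries. Cells with the profile of the CAS129 PSC libraries mixed into the cultures would bring these transcripts at 1 common share, but the 90th percentile was 11.8 times the 10th, and the SD of the log2 ratio was 1.22. The SD between the 2 single CAS129 PSC libraries was 0.79, which gives 0.51 for a ratio of the means of 3 and 2 libraries. This 0.51 rests on PSC levels of at least 20 CPM, while MN levels were as low as 0 for Spic and 0.457 CPM for Dpys. Noise at such levels is not in it, so it and the 1.22 are not fully comparable. PSC libraries under an MN label are argued against by synaptic genes, of which 23 of 28 were higher in each CAS129 MN library than in every PSC library. Undifferentiated or dividing cells in a state unlike that of the PSC libraries may be present and were not tested, and neither was an effect of the hybrid genome.

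Genes at 0 in every hybrid library were weighed next. Of 8779 genes with at least 10 CPM in the other genotypes, 368 had 0 counts in all 6 hybrid libraries, among them Pgk1, Actg1, Mapt and Rpl11. Too few reads are argued against by the lowest expected count of such a gene, 541, and a loss like that of genes switched off between cell types by the share at exactly 0 among genes over 100-fold lower in hybrid MN, 87.4% against 20.7% (Fisher's exact p = 1.5e-25). Families that share the part of a symbol before its digits were lost whole in 9 of 680 cases, such as all 8 March and all 8 Sept genes. At most 2 were lost whole in 10000 shuffles of the zeros over genes (permutation p = 1e-04, 1-sided, the smallest they can give). Of the 9, the Seleno family (all 9 genes) has no such digits and was grouped by hand. A different set of gene names or annotation in the counting of the hybrid libraries is a candidate explanation, and no biological one was tested beyond that. Such losses were not confined to the hybrids. Of 9115 genes with at least 10 CPM in 129 and CAST MN, 12 had 0 counts in all 9 BL6 libraries. Myadm, the largest rise of CAST against BL6 MN, had 0 counts in BL6 MN and 340 to 1170 CPM in the other MN groups. Fau stood at 250 CPM in BL6 MN and at 0 counts in those groups. Whether counting differed between BL6 and the other genotypes was not tested, also for Hspb1 and Meg3.

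Part of the genes that lie inside a gene on the opposite strand were low in 129 MN and 129CAS MN. In 129 MN, 64 of 233 such genes (27.5%) were over 8-fold lower than in BL6 MN, against 0.978% of 6952 genes without an overlap (Fisher's exact p = 3.3e-62), and in CAST MN 1.29% against 0.964% (p = 0.5). Smaller excesses were found in CAS129 MN (7.73% against 4.11%, p = 0.012) and CAS129 PSC (9.43% against 4.82%, p = 0.0054), by the same exact test. Of the 64 genes low in 129 MN, 55 were not low in CAS129 MN, while 59 were low in 129CAS MN. CAS129 cells also hold a CAST genome, so an 8-fold cut there cannot by itself decide on low expression from a 129 genome. Both hybrids hold a CAST and a 129 genome, so a 129 genome alone would not set 129CAS MN apart from CAS129 MN. The median log2 difference from BL6 MN over the 64 genes was -5.01 in 129 MN and -0.09 in CAS129 MN. 129CAS MN is 1 library. Too few reads in the 129 MN and 129CAS MN libraries are argued against by their depth. The shallowest of these 3 libraries held 25.69 M counts, more than every other library. Reads told apart by strand in these 3 libraries and not in the others could give this pattern but not the excesses in CAS129, and it needs a kit that marks strand, which the labels do not name.

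Other splits of the samples were counted, with 100 splits for each comparison. For MN against PSC over 3 genotypes, 1 split, the real one, gave as many genes (11642, highest other 5624). For CAS129 against BL6 MN it was also 1 (8834, highest other 6). Replicates may not be separate cultures, so these splits cannot exclude chance differences between cultures or lines. For the trend over CAST genomes 2 splits gave as many, the real one with 439 and another with 1012, and a further split gave 415. The real count therefore lies within the range of the other splits, and edgeR called 0 genes for this trend without the BL6 libraries (1451 at an unadjusted p under 0.05) and 0 with a block for the replicate number (923). What these splits group together was not tested.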

How the results depend on the processing

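Fits without genes at 0 in a genotype, with thinned counts, and without the BL6, the hybrid or the CAS129 libraries were chosen after the data were seen. Of 26010 values of named genes under an alternative, 23991 kept their direction and their side of the threshold, 1976 lost the call, 40 gained one and 3 reversed. Fos in MN against PSC of BL6 was -2.19, and ran from -3.24 without BL6 PSC replicate 2 to 2.15 without replicate 1. In the trend over CAST genomes, Hspb1 was 1.81 without the BL6 libraries and Lin28a -0.29 without the hybrid libraries, neither past the threshold. The causes were not tested. Camera called 3 list tests with an estimated correlation and 97 with the preset one.

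A threshold of 0.01, stricter by construction, left 1266 genes for the difference of the MN change between CAS129 and BL6. It left 460, 1816 and 1131 for CAST against BL6, CAS129 against BL6 and CAS129 against CAST in PSC. In MN it left 3425 for 129 against BL6, 824 for CAST against BL6, 2261 for 129CAS against CAS129 and 52 for the trend. A minimum 2-fold change left 3176 for 129 against BL6, 5364 for CAS129 against BL6 and 271 for the trend. A fit of all 8 groups called 3532, 5487 and 3523 in the 3 PSC comparisons and 685 for the trend, and a fit of CAST and BL6 MN alone 895. DESeq2 called 2222 for CAST against BL6 in PSC and 2071 for the trend, and without a filter the former was 2682. Without genes at 0 in a genotype, CAS129 against CAST in PSC called 946. The trend called 165 without the hybrid libraries and 0 by edgeR without the BL6 libraries (1451 at an unadjusted p under 0.05). The cause was not tested for these.

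Leaving out 1 library at a time gave 1409 to 3664 genes for the difference between CAS129 and BL6. In PSC it gave 316 to 2105 for CAST against BL6, 2132 to 3658 for CAS129 against BL6 and 1112 to 1320 for CAS129 against CAST. In MN it gave 2764 to 6324 for 129 against BL6, 1550 to 3805 for CAST against BL6 and 196 to 6109 for the trend. A group left with 1 library is assumed to vary like the others. In MN against PSC over 3 genotypes the range was 11190 to 11554. Simulated 2-fold changes between CAST and BL6 in PSC, with 2 libraries each, were recovered in 1.5% of genes.

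The labels do not say that a replicate number marks a shared culture or day, and correlations of deviations between samples of the same number ran from -0.162 to 0.576, so not every pair deviated together and the fits were made without a block. In PSC they were 0.345 for BL6 and CAST, 0.452 for CAST and CAS129, and -0.017 for BL6 and CAS129. The mesenchyme list mean was higher in PSC replicate 1 than in replicate 2 in BL6 (6.31 and 3.95), CAST (6.17 and 4.85) and CAS129 (5.25 and 3.31). So were those of the immediate early and stress list (6.55 and 5.13, 5.77 and 4.78, 5.64 and 4.23) and the activin list (4.35 and 3.92, 4.11 and 3.55, 3.7 and 3.05), and that of glycolysis was lower (8.8 and 9.59, 8.22 and 9.22, 8.9 and 9.32). These shifts are a hint from the data that PSC replicates of the same number share something, which the labels do not state. With a block for the replicate number, 1886 genes were called for the difference between CAS129 and BL6, 766 for CAST against BL6 in MN, and 0 by edgeR for the trend (923 at an unadjusted p under 0.05). In PSC the block gave 2161 for CAST against BL6, 4312 for CAS129 against BL6 and 2426 for CAS129 against CAST.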

Other observations

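The test of a hypothesis in this part, and the MN levels compared in this paragraph, were chosen after the values were seen. In the CAST MN library and the 129CAS MN library, Cartpt, a neuropeptide gene, stood at 398 and 314 CPM, against 31.3 CPM in BL6, 64.1 CPM in 129 and 59 CPM in CAS129 MN. Sst, which encodes somatostatin, stood at 76.3 CPM in BL6 MN and 2.39 CPM in 129 MN. Slc7a11, the cystine transporter gene, stood at 591 CPM in CAST and 345 CPM in CAS129 MN, against 10.8 CPM in BL6, 4.35 CPM in 129 and 4.28 CPM in 129CAS MN.

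Meg3, Rian and Mirg, maternally expressed RNAs of the imprinted Dlk1-Dio3 cluster, were lower in every BL6 MN library than in every other MN library. Mirg, chosen after its values were seen, stood at 1.98 CPM in BL6 MN and 34.3 to 61.5 CPM in the other MN groups. A loss of maternal expression in BL6 limited to this cluster was set as a hypothesis. Of 5 genes elsewhere taken as maternally expressed (H19, Igf2r, Cdkn1c, Phlda2 and Grb10), 0 were lower in every BL6 MN library than in every other MN library. Which copy of each gene is expressed in MN was not tested, and a gene not expressed from the maternal copy there would not bear on the hypothesis. Phlda2 could not have been lower, with 0 counts in CAST MN, so the count rests on at most the other 4. This is a count over libraries with no test tool, which leaves the hypothesis open, and a strain difference in the cluster's expression may give the same values.

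The log2 difference between CAS129 and BL6 in PSC correlated with that in MN across 12852 genes (r = 0.852, rho = 0.557), and across 12158 genes without those at 0 in a genotype (r = 0.611, rho = 0.485). For CAST against BL6 the same values were r = 0.483 and rho = 0.186, and r = 0.329 and rho = 0.168. Genes are not independent replicates, and no library is shared between the PSC and MN fits.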
